A study of Mus musculus with 43 samples.

How the data were processed

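Methylated DNA was immunoprecipitated from mouse cells and tissues and hybridised, against input DNA of the same sample, to two-colour CpG island arrays. The sources used here give 43 arrays: 16 of 8 adult tissues (age 3 months), 5 of embryos, 6 of 5 ES lines, 6 of 4 cell types differentiated in culture, 4 of 2 teratoma types, 3 of placentas, 2 of islet tumour lines and 1 of beta cells. Groups, parent lines, sex and replicate numbers were taken from the labels. The channel text of the E19.5 placentas names E14.5 for the bound channel, and the stage of the sample title was used.

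Per the file headers, the deposited scanner files hold fluorescence intensities of both channels (Cy3 input, Cy5 bound DNA) that Feature Extraction had background-subtracted, detrended and dye-normalised with a linear factor. Some headers state the build mm9 and others none. The authors also deposited 1 score per probe and array in a joint table, which behaves as a log ratio standardised within each array (column medians between −0.315 and −0.029, Pearson r with the log2 ratios computed here between 0.894 and 0.991, across probes, which are not independent replicates); whether an intensity-dependent step was used to make it is not given in the sources used here. No pair of arrays was identical, and 0 columns belonged to no sample.

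The files held either 97651 or 88737 probes, and for brain, kidney, liver, muscle, lung and spleen replicate 1 had the larger number and replicate 2 the smaller. Of 88737 probes common to all files, 416 without an mm9 position were left out. The log2 ratio of processed bound over input signal was centred on the array median over 85850 autosomal probes, with outlier spots set to missing. Regions were runs of at least 3 probes with starts at most 500 bp apart: 13829 regions, 13444 autosomal and 385 on the X, with a median of 5 probes and 644 bp. Region values are means over probes. Of 12564 gene names in the files 11201 were current, 1280 were updated by synonym and 83 were kept. Dye swaps were not used, so a dye effect common to all arrays stays in the values but cancels in differences.

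Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests), with data.table (version 1.17.8) and jsonlite 2.0.0. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the figures. The 2 arrays of a type were averaged, and 1 coefficient per class was fitted over all classes; placenta arrays were kept apart. Normal tissue is the mean of the adult and embryo coefficients. Derivatives were compared with their own line with the line as a block. Adult tissues were compared by a moderated F test over arrays and each with the other 7, and females with males within tissue. A region was called at a Benjamini-Hochberg adjusted p under 0.05 over the autosomal regions and a difference of at least 1 (log2).

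Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 23 lists per comparison. The lists were imprinted loci, germ cell, pluripotency, hox, developmental transcription factor (Polycomb targets in ES cells), endoderm, mesoderm, islet, trophoblast, housekeeping, protocadherin and tumour suppressor genes, DNA methylation enzymes, genes of the 2-cell-like state, and genes of fibroblasts, blood, brain, liver, muscle, kidney, lung, colon and pancreas. A gene with several regions was represented by the region nearest its start. The groups, tests, lists, call and naming rule were set before the data were examined. Named are the 8 called regions with the largest positive and the 8 with the largest negative difference among those whose group ranges do not overlap, the 4 members of a list with the largest differences, and per tissue the 3 regions furthest below and the 1 furthest above the other tissues. Regions called among tissues by the F test are all named because they number 12.

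At regions called higher in ES cells without the parent line, the ratio is the median of (sample minus normal) over (other ES lines minus normal). Enriched regions had a value of 1 or more, and their numbers were compared by an exact permutation test over 8568 splits.

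Alternatives were normexp background correction (offset 50, median signals), quantile normalization, division of each array by the distance between its percentiles 25 and 95, input well above background, at least 5 probes per region, medians of probes, the deposited scores, other size limits, single probes, batch as a block (5 software and protocol batches), random blocks for slide, scan day and type, sex as a covariate, and leaving out each unit or array. The methods were tested on simulated data with 100 changed regions: at a change of 1.5 the fit recovered 86% of them for ES cells, 84% for cells differentiated in culture, 61% for teratomas, 68% for placentas, 75% for islet lines, 42% for beta cells, 19% for cells in culture against their own line and 2% for teratomas against theirs. A simulated ratio of 0.5 was recovered as 0.488.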

Results

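DNA methylation at mouse CpG islands was measured by immunoprecipitation of methylated DNA (mDIP) and two-colour arrays, on which antibody-bound DNA was hybridised together with input DNA of the same sample. The 43 arrays held 16 arrays of 8 adult tissues (colon, pancreas, brain, kidney, liver, lung, muscle and spleen), 5 arrays of embryos from E8.5, E9.5, E10.5, E11.5 and E12.5, and 6 arrays of the embryonic stem (ES) cell lines EB5, J1, TT2, D3 and C4. Cells differentiated from ES cells in culture gave 6 arrays: embryoid bodies and retinoic acid treated cells of line TT2, and endoderm and mesoderm of line EB5. Teratomas, the tumours that ES cells form after injection into mice, gave 4 arrays from lines C4 and D3. Another 3 arrays held placentas of E14.5 and E19.5, 2 held the islet tumour lines Min6 (beta cell derived) and alphaTC (alpha cell derived), and 1 held purified beta cells. The value of a region is the mean log2 ratio of bound to input DNA over its probes, with the array median at 0, so a higher value stands for more methylated DNA. Between 62.5% and 99.9% of the probes of an array were well above background in the input channel and 59.3% or more in the bound channel. The number of arrays per class limits the precision. The sources used here do not state that replicates came from separate animals or cultures, so p-values measure the spread between these samples. Positions are in mm9.

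On average 13.5% ± 1.7 (SD, n = 8) of autosomal regions had a value of 1 or more in adult tissues, 12.1% ± 1.4 (n = 5) in embryos, 13.5% ± 2.7 (n = 5) in ES lines and 16.1% ± 3.0 (n = 4) in cells differentiated in culture. The shares were 13.5% ± 4.1 (n = 2) in teratomas and 17% ± 0.5 (n = 2) in placentas. Beta cells had 11.8%, and the islet tumour lines 28.0% ± 3.8 (n = 2). ES lines had 1820 ± 365 such regions and normal tissues 1743 ± 226 (n = 13), a difference of 77.5 that did not pass the exact two-sided permutation test (p = 0.586, 8568 splits). After each array was divided by its own spread the difference was 617 (exact permutation p = 0.000467). The cut-off stayed at 1, so the division lowered it for arrays of small spread and raised it for those of large spread. ES arrays had spreads between 2.51 and 3.84, and normal arrays between 2.57 and 5.24. This second test therefore cannot tell more enriched regions in ES lines from the changed cut-off.

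The first comparison asked where undifferentiated ES cells differ in methylation from normal tissues. Among the regions higher in ES cells was the start of Atf7ip, which encodes a partner of the histone methyltransferase SETDB1 (chromosome 6, 136467067 to 136467757, inside the gene), with 3.30 ± 0.85 in ES lines (SD, n = 5) and 0.10 ± 0.29 in normal types (n = 13), a difference of 3.17 ± 0.29 (SE, adjusted p = 1.19e-07). The neurofilament gene Nefm (chromosome 14, 68741536 to 68743210, inside the gene) was higher by 2.98 ± 0.37 (adjusted p = 3.67e-06), and Slitrk1 by 2.97. The vesicular GABA transporter gene Slc32a1 was higher by 2.64 and Rbfox3, the gene of the neuronal marker NeuN, by 2.61. The prostaglandin receptor gene Ptger4, the cell cycle regulator Rgcc and the microfibril gene Mfap2 were higher by 2.61, 2.58 and 2.37. In the other direction, the zinc finger gene Zfp282 (chromosome 6, 47854684 to 47855452, inside the gene) had 0.38 ± 0.74 in ES lines and 5.09 ± 1.02 in normal types, a difference of −4.62 ± 0.40 (adjusted p = 4.59e-08). The zinc finger genes Zfp46, Zfp865 and Zscan2 differed by −4.15, −4.13 and −3.77, and Mbd3, which encodes a subunit of the NuRD complex, by −3.88. All 16 of these regions, with the imprinted genes Mcts2, Zrsr1 and Peg10 among them, kept their direction and an adjusted p under 0.05 in each alternative setting that was run.

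Imprinted loci were 1 of 4 lists placed lower. Of 23 measured genes at imprinted loci, 13 fell in ES cells and 0 rose (13 and 0 adjusted over the list alone), with a median difference of −1.19. After normexp the median was −0.31 with 9 lower, in the series matrix values −0.64 with 9 lower of 19 measured, and with batch as a block −1.17 with 12 lower. The measured region of a gene need not be the one that carries the imprint: 7 of the 23 lay near the array median in normal types, between −0.21 for H13 and 0.43 for Dlk1, and had little room to fall. The start of the retrogene Mcts2 (chromosome 2, 152512463 to 152513054, promoter) had 0.17 ± 1.32 in ES lines and 4.39 ± 0.89 in normal types (difference −4.26 ± 0.45, adjusted p = 4.18e-07). Zrsr1 (chromosome 11, 22872000 to 22873052) differed by −4.24, Peg10 (chromosome 6, 4697308 to 4698444) by −3.90 and Impact (chromosome 18, 13131830 to 13132313) by −3.84 (adjusted p = 4.84e-05), all 3 inside the genes. The lines differed: at Impact, with a mean of 0.60 ± 2.06 in ES lines, D3 had 4.11, near the normal mean of 4.39, and the other 4 lines between −0.82 and 0.74. Line TT2, whose array had the largest spread of the ES arrays, was the highest at Mcts2, Zrsr1 and Peg10, with 2.19, 2.20 and 2.16. The camera test placed the list below the other regions (adjusted p = 3.25e-06, adjusted p = 0.293 with an estimated correlation). With each array divided by its own spread 11 genes were called lower and 1, Peg13, higher, with Zrsr1 at −4.19, Mcts2 at −3.91, Peg10 at −3.74 and Impact at −3.39.

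**Figure D1:**
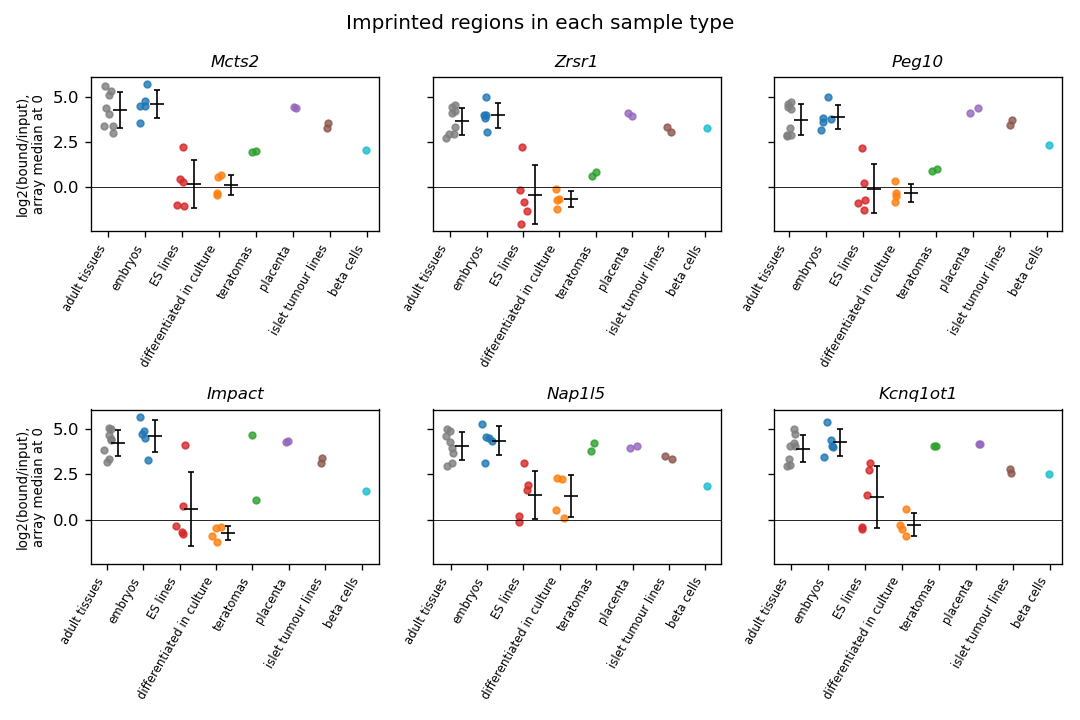
Region values (log2 of bound over input DNA, array median at 0) at 6 imprinted genes; each point is 1 sample type, and bars show mean and SD for classes of more than 2 types. At Mcts2 the ES lines had a mean of 0.17 and the normal types 4.39, and at Impact the cells differentiated in culture had −0.75 against 4.39.

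Genes used in germ cells were lower as well: of 30 measured, 17 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of −1.40 (camera adjusted p = 2.51e-06, adjusted p = 0.361 with an estimated correlation). Dmrtb1, a regulator of the entry into meiosis, fell by 2.97 (adjusted p = 8.56e-06), Boll by 2.63, Stk31 by 2.47 and the germ cell helicase gene Ddx4 by 2.44. With each array divided by its own spread the median was −0.32 and 7 genes were called. Of 11 protocadherin cluster genes 5 fell (5 adjusted over the list alone), led by Pcdha4 with −2.47 and Pcdha12 with −2.35. Line TT2, with 1 array, stood apart on this list, with a median level of 3.31 against 0.89 to 1.37 in the other ES lines. That array also had the largest spread of the ES arrays (3.84 against 2.51 to 3.06), so enrichment cannot be told apart from the line. With batch as a block 3 were lower, after quantile normalization or division by spread 2, after normexp 1 and in the series matrix values 0 of 5 measured. The protocadherin median of −0.46 changed sign to 0.01 with arrays divided by their spread and to 0.07 in the series matrix values (camera adjusted p = 0.027, adjusted p = 0.438 with an estimated correlation). Of 12 pluripotency genes only Utf1 was called, with −1.09 (adjusted p = 0.00033), a call lost against embryos alone; the list median was −0.37 (camera adjusted p = 0.000569, adjusted p = 0.257 with an estimated correlation).

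Developmental transcription factors were placed higher than other regions by camera (adjusted p = 2.51e-06, adjusted p = 0.257 with an estimated correlation), although 5 of 146 were called higher and 0 lower (5 and 0 adjusted over the list alone). After normexp 0 were called, after quantile normalization 8 higher, with arrays divided by their spread 11 higher and 3 lower, and with batch as a block 2 higher. Their median was −0.03 and their mean 0.05, and the median changed sign to 0.09 after quantile normalization and to 0.01 with batch as a block. The homeobox genes Lhx3 and Vsx2 were each higher by 1.92 (adjusted p = 1.07e-06 and 1.59e-07), Dbx2 by 1.36 and Tbx4 by 1.21; the calls of Dbx2 and Tbx4 were lost with batch as a block. Brain genes (2 of 25 higher, Nefm and Tbr1 by 1.29) had a median of −0.02 and a mean of 0.20 (camera adjusted p = 4.2e-05, adjusted p = 0.0599 with an estimated correlation); this median changed sign to 0.14 after quantile normalization, to 0.04 with arrays divided by their spread and to 0.01 with batch as a block. Mesoderm genes (2 of 25 higher, the myogenic regulator Myod1 by 1.58 and Lyl1 by 1.66) and blood genes (2 of 14 higher) were also placed higher, with adjusted p = 0.00377 and 0.0295 (0.257 and 0.361 with an estimated correlation). The blood median of −0.03 changed sign to 0.01 with arrays divided by their spread and to 0.07 with batch as a block.

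The remaining 15 lists were not called in ES cells. Hox genes (1 of 37 higher, 3 lower), trophoblast genes (1 of 17 lower), tumour suppressor genes (2 of 35 lower), liver genes (1 of 8 lower), muscle genes (1 of 14 higher), lung genes (1 higher and 1 lower of 12) and pancreas genes (1 of 12 higher) had camera adjusted p between 0.0718 and 0.868. DNA methylation enzymes had 1 of 12 lower and a median of −0.15 (adjusted p = 0.266), and genes of the 2-cell-like state had 1 of 4 lower and a median of −0.58 (adjusted p = 0.0818). Limma called 0 endoderm, islet, housekeeping, fibroblast, kidney and colon genes, with 7, 4, 18, 3, 5 and 2 at an unadjusted p under 0.05.

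In total 1021 of 13444 autosomal regions differed between ES cells and normal tissues by limma, 218 higher and 803 lower. With the scanner and software batch as a block 523 were called (166 higher, 357 lower), of which 129 and 347 were called in the same direction without it. The median of the 218 higher regions went from 1.30 ± 0.28 (SE) to 1.32 ± 0.36 with the block. That of the 803 lower ones went from −1.64 ± 0.35 to −1.30 ± 0.43. The split depended on the scaling, with 446 higher and 373 lower after quantile normalization, 561 higher and 920 lower with arrays divided by their spread, and 32 higher and 255 lower after normexp background correction. The median difference over all regions, −0.14 here, moved by more than 0.1 to −0.01 after quantile normalization. Within the batches that held an ES line and normal samples, regions called higher without that line differed by a median of 0.83 for EB5, 0.90 for J1 and 1.62 for TT2, and regions called lower by −1.15, −1.03 and −0.90.

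Cells differentiated in culture were compared with normal tissues to ask whether differentiation brings the normal pattern. Among called regions with a gene name and group ranges that do not overlap, the 8 furthest below the normal level all lay at imprinted genes. Impact had −0.75 ± 0.40 in the cells (SD, n = 4) and 4.39 ± 0.77 in normal types (n = 13), a difference of −5.18 ± 0.64 (SE, adjusted p = 7.57e-06). Zrsr1 differed by −4.47, the zinc finger gene Peg3 (chromosome 7, 6682111 to 6683212, inside the gene) by −4.44, the noncoding RNA gene Kcnq1ot1 (chromosome 7, 150481208 to 150482535, inside the gene) by −4.39, Mcts2 by −4.32, the adaptor gene Grb10 by −4.20, Peg10 by −4.14 and Gnas by −3.76. Higher were Slc32a1 by 2.98 ± 0.40, the cartilage protein gene Cilp2 by 2.91, Slitrk1 by 2.89, Ptger4 by 2.64, the gelatinase gene Mmp9 (chromosome 2, 164774623 to 164775362, inside the gene) by 2.64 ± 0.24 (adjusted p = 1.85e-07). The homeobox gene Irx5 was higher by 2.62, Rbfox3 by 2.56 and Atf7ip by 2.49. Normexp background correction ended the calls of Slitrk1, Ptger4 and Gnas.

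Of 23 imprinted genes 15 fell in these cells and 0 rose (15 and 0 adjusted over the list alone), with a median of −1.39 (camera adjusted p = 5.99e-12, adjusted p = 0.137 with an estimated correlation). In the series matrix values the median was −0.64 with 8 lower of 19 measured, and after normexp −0.81 with 10 lower. Germ cell genes had 20 of 30 lower (21 adjusted over the list alone), among them the synaptonemal complex genes Sycp1 and Sycp2 with −1.99 and −1.91 and the testis gene Brdt with −1.90, and a median of −1.53 (camera adjusted p = 8.93e-08, adjusted p = 0.216 with an estimated correlation). The germ cell calls depended on the processing: 0 were called after normexp background correction, 1 higher and 1 lower after quantile normalization or division by spread, and 3 lower with batch as a block. Developmental transcription factors had 7 of 146 higher and 0 lower (7 and 0 adjusted over the list alone), with Vsx2 at 2.26, Lhx3 at 1.76, Dbx2 at 1.52 and Tbx4 at 1.50. Their median of 0.03 changed sign to −0.03 with arrays divided by their spread and to −0.04 in the series matrix values (camera adjusted p = 1.43e-07, adjusted p = 0.137 with an estimated correlation). Protocadherin genes (5 of 11 lower) had a median of −0.35, which changed sign to 0.05 with arrays divided by their spread (camera adjusted p = 0.0217, adjusted p = 0.389 with an estimated correlation). Batch as a block ended the camera calls of the protocadherin, islet and tumour suppressor lists (adjusted p = 0.0682, 0.0927 and 0.0927). Brain genes (3 of 25 higher, 1 lower) had a median of 0.10 (adjusted p = 5.32e-05, adjusted p = 0.0656 with an estimated correlation), and endoderm genes (0 of 19 called by limma, 7 at an unadjusted p under 0.05) a median of 0.24 (adjusted p = 0.00211, adjusted p = 0.137 with an estimated correlation). Of the 14 lists that camera called here, 0 were called with an estimated correlation.

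The limma fit called 1267 regions, 446 higher and 821 lower, against 547 with batch as a block (438 higher, 109 lower), of which 351 and 105 were shared. Scaling changed the split to 824 higher and 95 lower with arrays divided by their spread, 463 and 114 after quantile normalization, 239 and 54 in the series matrix values and 56 and 24 after normexp. Within the single batch that held 4 of these types and all adult tissues, 1022 regions differed from adult tissues (429 higher, 593 lower), and 912 (369 higher, 543 lower) with all arrays.

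Teratomas were compared with normal tissues in the same way. Nefm had 4.03 ± 0.05 in teratomas (SD, n = 2) and −0.55 ± 0.12 in normal types (n = 13), a difference of 4.58 ± 0.54 (SE, adjusted p = 0.000108), and 3.94 with batch as a block (adjusted p = 0.000102). Higher were also Cyb5b by 3.30, the hormone precursor gene Pomc by 2.89, Spata3 by 2.75, 2810429I04Rik by 2.63, Slc16a8 by 2.53, B3glct by 2.42 and the platelet glycoprotein gene Gp5 by 2.41. Lower were Tmem267 by −3.81, Zrsr1 by −3.07, 3 regions of Gnas, the nearest to 0 of them by −2.74, Peg10 by −2.86, Grb10 by −2.75 and Mcts2 by −2.47. Of 23 imprinted genes 4 fell and 0 rose (4 and 1 adjusted over the list alone), namely Zrsr1, Peg10, Mcts2 and Igf2r, the last by −2.03. The imprinted median was −0.04, changed sign to 0.02 after normexp, and was −0.45 with batch as a block (camera adjusted p = 0.818, and 0.00412 with the block). None of the 23 lists was called by camera, with imprinted, hox, muscle, pluripotency and germ cell genes at unadjusted p = 0.19, 0.0316, 0.0916, 0.0815 and 0.161.

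In total 561 regions were called by limma in teratomas (216 higher, 345 lower), 15 with batch as a block (8 higher, 7 lower; 2 and 1 shared) and 31 with arrays divided by their spread. Without the C4 teratomas 5 were called, without the D3 teratomas 1182 and without C4 teratoma replicate 1 849. Nefm and Grb10 (−3.05, adjusted p = 0.0189) kept their calls with batch as a block, and the other 14 regions named here did not. The larger direction turned with the processing: 307 higher and 37 lower with input well above background on every array, 211 and 175 after quantile normalization and 39 and 37 in the series matrix values. The median over all regions was −0.13, −0.02 after normexp, −0.01 after quantile normalization and 0.04 with batch as a block. With the block the median of the 216 higher regions went from 1.56 ± 0.42 (SE) to 1.19 ± 0.62 and that of the 345 lower ones from −1.23 ± 0.33 to −0.37 ± 0.46.

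The regions higher in ES cells were then followed into the derivatives, with regions called without the parent line and the ratio set to 1 where the derivative differed from normal tissue as much as the other ES lines. Embryoid bodies had a median ratio of 1.27, mesoderm 1.03, endoderm 0.978 (0.789 and 1.17 in its replicates) and retinoic acid treated cells 0.626 (0.5 and 0.723). Teratomas had 0.134 (0.071 and 0.262) for C4 and 0.006 (0.004 and 0.001) for D3. Over the 6 derivatives the median was 0.802, with a spread of 0.169 (SD) between replicates. The ES lines themselves had 0.865 ± 0.268 (SD, n = 5), adult tissues 0.06 ± 0.064 (n = 8) and embryos −0.05 ± 0.042 (n = 5). The value lay above every normal type at 83.6% of the regions in embryoid bodies, 83.7% in endoderm, 80.2% in mesoderm, 60.5% in retinoic acid treated cells, 40.3% in C4 teratomas and 15.2% in D3 teratomas.

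**Figure D2:**
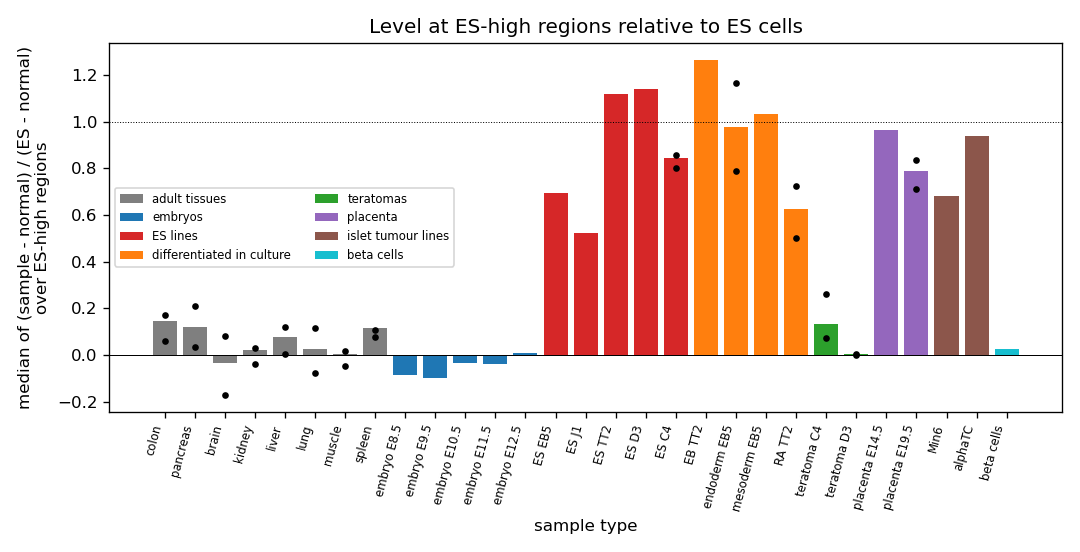
Median ratio at regions higher in ES cells, per sample type, where 0 is the normal level and 1 (dotted line) the level of the other ES lines; bars are medians over regions and dots the 2 replicate arrays where a type has them. Cells differentiated in culture had ratios between 0.626 and 1.27, and teratomas 0.134 and 0.006.

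The ratios moved with the processing, and in some settings C4 teratomas lay within the replicate spread of a cell type in culture. With input well above background on every array they had 0.635, retinoic acid treated cells 0.667 and D3 teratomas 0.24. With no size limit C4 teratomas had 0.272 and retinoic acid treated cells 0.346. Normexp gave 1.50 for embryoid bodies, 0.834 for retinoic acid, 0.478 for endoderm and 0.24 for mesoderm, and quantile normalization 0.579, 0.444, 0.761 and 0.771, beside 0.159 and 0.108 for C4 teratomas and 0.099 and 0.033 for D3 teratomas. With batch as a block C4 teratomas had 0.436 and D3 teratomas 0.113, and C4 teratomas had 0.523 over regions of at least 5 probes (retinoic acid treated cells 0.665) and 0.311 in the series matrix values. With normal types split between the call and the measurement (20 draws) the medians were 1.27, 0.943, 0.985, 0.65, 0.108 and −0.012 in the order embryoid bodies, endoderm, mesoderm, retinoic acid, C4 and D3 teratomas.

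Each derivative was also set against its own ES line, to ask what changes on differentiation. In teratomas Mbd3 had 4.31 ± 0.35 (SD, n = 2) and −0.26 ± 1.67 in the parent lines (n = 2), a difference of 4.57 ± 0.82 (SE, adjusted p = 0.0232), and Zfp282 was higher by 4.11 ± 0.40 (adjusted p = 0.0048). Napepld, Zfp467, Bcl7a, the kinase regulator gene Pik3r4, Rasgrp2 and the planar polarity gene Prickle1 were higher by 4.40, 4.36, 4.28, 4.22, 4.00 and 3.97. The nuclear receptor gene Nr2f1 (chromosome 13, 78320494 to 78320770, downstream) fell by 3.71 (adjusted p = 0.00783), the apoptosis regulator gene Bcl2 by 3.43, the chloride transporter gene Slc12a5 by 3.34, the homeobox genes Emx2, Hoxc4, Barhl1 and Lbx1 by 3.05, 2.97, 2.96 and 2.91, and Mfap2 by 2.78. Germ cell genes had 9 of 30 higher and 0 lower (22 adjusted over the list alone), among them Piwil2 by 2.36 (adjusted p = 0.0162), Pramel1 by 2.23 and Sycp3 by 2.20, with a median of 1.56 (camera adjusted p = 3.26e-09, adjusted p = 0.43 with an estimated correlation). With batch as a block 12 were called, but 0 after normexp, quantile normalization or division by spread and 0 in the series matrix values, with medians of 0.93, 0.42, 0.40 and 0.86. Imprinted genes had 1 of 23 higher, Trappc9 by 2.03 (4 adjusted over the list alone), with Mcts2 at 2.34 (adjusted p = 0.0684). Their median of 1.25 changed sign to −0.08 with arrays divided by their spread (camera adjusted p = 0.00146, adjusted p = 0.43 with an estimated correlation).

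Developmental transcription factors had 3 of 146 lower in teratomas than in their ES line, Vsx2 by −2.17, Lhx3 by −1.92 and Pax1 by −1.41 (1 adjusted over the list alone). Their median of −0.06 changed sign to 0.04 after normexp, 0.07 with division by spread and 0.01 in the series matrix values (camera adjusted p = 4.74e-09, adjusted p = 0.43 with an estimated correlation). Of 11 protocadherin genes 2 were higher (5 adjusted over the list alone), Pcdhgb8 by 3.70 and Pcdhga12 by 3.14. Their median of 1.21 changed sign to −0.05 after quantile normalization and to −0.01 with division by spread (camera adjusted p = 0.00127, adjusted p = 0.43 with an estimated correlation). Of the 13 lists camera called here, 0 were called with an estimated correlation. The limma fit called 516 regions in teratomas (420 higher, 96 lower), 460 with batch as a block (340 and 120, 279 and 74 shared), 83 after quantile normalization (31 and 52, 31 and 32 shared), 494 with division by spread (323 and 171, 59 and 84 shared) and 0 after normexp, where 0 of the named calls remained. Without the C4 pair 99 were called, without the D3 pair 155 and without endoderm 301.

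Cells differentiated in culture had 0 regions called against their own ES line by limma, with 1227 at an unadjusted p under 0.05, and 3 without retinoic acid replicate 2. Camera placed the imprinted list (median −0.91, adjusted p = 0.00135) and the germ cell list (median −0.40, adjusted p = 0.000843) lower, and kidney genes higher with a median of 0.07 that changed sign to −0.19 with batch as a block (adjusted p = 0.00418). All 3 calls were lost with an estimated correlation (adjusted p = 0.818 each). The imprinted median was −0.24 with batch as a block and −0.28 in the series matrix values, and the germ cell median was −0.06 after quantile normalization.

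Embryos were compared with adult tissues as the normal developmental difference. BC068157 (chromosome 8, 4206417 to 4206764, inside the gene) had −0.13 ± 0.48 in embryos (SD, n = 5) and 4.36 ± 0.93 in adult tissues (n = 8), a difference of −4.50 ± 0.38 (SE, adjusted p = 2.34e-08), and the kinase gene Rps6ka4 (chromosome 19, 6904359 to 6906086, inside the gene) differed by −3.71 ± 0.27 (adjusted p = 8.08e-09). Lower were also the zinc finger gene Zfp316 by −4.06, the microRNA gene Mir219a-2 by −3.75, Tmem200b by −3.70, Mab21l1 by −3.58, Plekhh3 by −3.57 and Myorg by −3.56. Higher in embryos were Zfp36, whose product promotes mRNA decay, by 1.71 ± 0.29 (adjusted p = 0.000337), the synaptic vesicle gene Rab3a by 1.59, Ocel1 by 1.46 and Cmtm7 by 1.43. Smaller differences were seen at the necroptosis gene Mlkl by 1.39, Tmed4 by 1.37, the lysosomal glucosidase gene Gaa by 1.31 and the hyaluronan synthase gene Has1 by 1.27. Only BC068157 (−5.15 ± 0.95) and Rps6ka4 (−3.53 ± 0.66) of these 16 regions kept their calls with batch as a block, each with adjusted p = 0.0206. The other 6 lower regions stayed between −4.22 and −3.17, with larger errors (0.83 to 1.04) and adjusted p between 0.0582 and 0.295. The 8 higher ones had between 0.43 and 1.79 (adjusted p between 0.322 and 0.951).

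Hox genes had 6 of 37 lower and 0 higher (6 adjusted over the list alone), with Hoxa3 at −3.15 (adjusted p = 5.81e-05), Hoxa5 at −2.75, Hoxb3 at −2.57 and Hoxd4 at −2.17, and a median of −0.42 (camera adjusted p = 2e-16, adjusted p = 0.0436 with an estimated correlation). Developmental transcription factors had 7 of 146 lower and 0 higher (7 adjusted over the list alone), with Hand1 at −2.24 (adjusted p = 3.25e-06), Tbx4 at −2.01, Cdx1 at −1.89 and Nr2f2 at −1.29, and a median of −0.20 (camera adjusted p = 3.08e-16, adjusted p = 0.0192 with an estimated correlation). These medians were −0.70 and −0.37 with batch as a block, where camera called both lists and limma called 0 of their genes. Mesoderm genes (2 of 25 lower) and lung genes (2 of 12 lower) had medians of −0.19 and −0.38 and were called with adjusted p = 0.00582 and 0.00769 with an estimated correlation. The endoderm, tumour suppressor, blood, brain, kidney and pancreas lists were called lower both ways, although batch as a block ended the tumour suppressor call (adjusted p = 0.128), and the trophoblast and muscle lists were lost with an estimated correlation (adjusted p = 0.102 and 0.124). The limma fit called 404 regions (73 higher, 331 lower) and 9 with batch as a block (0 higher, 9 lower, 7 of them shared). With the block the median of the 331 lower regions went from −1.67 ± 0.33 (SE) to −1.96 ± 0.84 and that of the 73 higher ones from 1.22 ± 0.29 to 0.76 ± 0.61. The median over all regions moved to −0.11 with the block. Adult tissues lay in 1 batch, 4 of the 5 embryos in another and the E8.5 embryo in yet another. No embryo shared a batch with an adult tissue. Splits under other scaling were 166 higher and 348 lower after quantile normalization and 3 and 57 after normexp.

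Placentas were compared with embryos to ask where extraembryonic tissue differs from the embryo. Of the 3 placenta arrays 2 were replicates of E19.5 (r = 0.987) and were not averaged. The SD, errors and p-values of this comparison therefore count that stage more than once. The tumour suppressor locus Cdkn2a (chromosome 4, 88922488 to 88922864, inside the gene) had 3.70 ± 0.11 in placentas (SD, n = 3 arrays) and −1.90 ± 0.33 in embryos (n = 5), a difference of 5.60 ± 0.49 (SE, adjusted p = 4.64e-09). Regions of developmental regulators followed: Alx4 was higher by 4.94, Six2 by 4.42, Lhx2 by 4.41, Pax6 by 4.25 and Sall1 (chromosome 8, 91549399 to 91549872, downstream) by 4.21 ± 0.33 (adjusted p = 1.08e-09), with Cir1 at 4.72 and Mir219a-2 at 4.24. Lower were the histone gene H2bc13 by −3.31, Tmem267 by −2.96, the helicase gene Ddx11 by −2.42, Slk by −2.25, Sbk1 by −2.20, Stk31 by −2.20, Zfp36 by −2.17 and Ccdc177 by −2.17. Sex differed between the groups by the labels, with 3 of 3 placentas female and 4 of 5 embryos male. The X-linked levels of the E8.5 and E9.5 embryos (1.66 and 2.21), labelled male, lay in the range of female adult arrays (1.33 to 4.14). Tmem267 was also lower in female than in male adult tissues, by −3.57. It was lower as well in teratomas and islet lines, whose X-linked levels lay within or below those of male adult arrays. With batch as a block 7 of the 8 higher regions kept their call, Cdkn2a with 5.33 (adjusted p = 0.000224), Lhx2 was lost (adjusted p = 0.0711), and 0 of the 8 lower regions were kept, H2bc13 having −0.79 (adjusted p = 0.792).

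Of 146 developmental transcription factors 64 rose in placenta and 0 fell (64 adjusted over the list alone), with a median of 0.87, and 44 rose with batch as a block, 25 after normexp and 20 of 122 measured in the series matrix values (camera adjusted p = 2.67e-56, adjusted p = 3.77e-05 with an estimated correlation). The endoderm regulator Sox17 was higher by 3.58 (adjusted p = 4.66e-09), Tbx4 by 3.66, Dbx1 by 3.51 and Foxl1 by 3.32. Hox genes had 20 of 37 higher and 0 lower (20 adjusted over the list alone), with Hoxd4 at 3.55, Hoxb3 at 3.50, Hoxd3 at 3.35 and Hoxd12 at 3.30, and a median of 1.25 (camera adjusted p = 1.63e-28, adjusted p = 0.00354 with an estimated correlation); the calls of Hoxd4, Hoxb3 and Hoxd3 were lost with batch as a block. Of these Hox genes 11 were higher with that block, 11 after normexp and 10 in the series matrix values. Mesoderm (8 of 25 higher), endoderm (6 of 19 higher, 1 lower) and brain (10 of 25 higher) lists had medians of 0.60, 0.76 and 0.71 and were called with adjusted p = 0.000106, 0.000469 and 5.73e-05 with an estimated correlation. Fibroblast, liver and colon genes had 3 of 12, 2 of 8 and 4 of 13 higher, with adjusted p = 0.00974, 0.00267 and 0.00354 with an estimated correlation. Of 17 trophoblast genes 2 rose, Ascl2 by 2.72 and Hand1 by 2.36, both regulators of trophoblast development. Their list had a median of −0.09 and a mean of 0.14, and the median changed sign to 0.17 after quantile normalization and 0.23 with batch as a block (camera adjusted p = 0.000711, adjusted p = 0.0733 with an estimated correlation). Housekeeping genes had 2 of 28 lower and a median of −0.31 (camera adjusted p = 0.0289, adjusted p = 0.313 with an estimated correlation and 0.191 with batch as a block).

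Germ cell genes had 6 of 30 lower in placenta (5 adjusted over the list alone), led by Stk31, with a median of −0.86 that changed sign to 0.67 with batch as a block (camera adjusted p = 0.0747). With that block Piwil1, at −1.73 in the main comparison, had 0.57, and Sycp2, at −1.58, had 1.36. The limma fit called 1782 regions in placenta (980 higher, 802 lower). With batch as a block 543 were called (479 higher and 64 lower, 406 and 20 shared). The median of the 980 higher regions went from 1.78 ± 0.34 (SE) to 1.92 ± 0.64, and that of the 802 lower regions from −1.21 ± 0.29 to −0.38 ± 0.48. Division by spread gave 849 higher and 419 lower and normexp 617 and 3. Lower regions outnumbered higher ones at smaller size limits, with 1434 higher and 2656 lower at a limit of 0.5 and 1501 and 3006 without a limit. The median over all regions was −0.19, 0.01 after normexp, −0.05 after quantile normalization, −0.07 in the series matrix values and 0.02 with batch as a block.

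The islet tumour lines were compared with adult tissues to ask how far tumour lines of 1 cell lineage differ from normal tissue. Cdkn2a had 4.47 ± 0.20 in the lines (SD, n = 2) and −0.79 ± 0.35 in adult tissues (n = 8), a difference of 5.26 ± 0.54 (SE, adjusted p = 1.73e-08). The cadherin gene Celsr3 (chromosome 9, 108734140 to 108735306, inside the gene) was higher by 4.51 ± 0.18 (adjusted p = 1.52e-15), the corepressor gene Ski by 4.92, the NMDA receptor gene Grin1 by 4.84, the Fc receptor gene Fcgr3 by 4.78, the neural factor Pou3f3 (chromosome 1, 42754743 to 42755470), Tmem132c by 4.59 and the neural crest factor Foxd3 by 4.38. Lower were Tmem267 by −3.98, the protocadherin gene Pcdh1 by −3.52 and the glutamate receptor gene Grm4 by −2.91. Further lower regions were the glutamate transporter gene Slc1a3 by −2.87, Dchs1 by −2.87, Fli1 by −2.78, Zfp423 by −2.67 and the synaptic vesicle gene Sv2c by −2.67. The calls of Tmem267, Dchs1 and Fli1 were lost with batch as a block, those of Dchs1 and Zfp423 without Min6, and those of Grm4, Slc1a3, Dchs1, Zfp423 and Sv2c after normexp.

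Of 146 developmental transcription factors 99 rose and 1 fell in the islet lines (99 and 1 adjusted over the list alone), with a median of 1.62 (camera adjusted p = 5.11e-31, adjusted p = 0.00214 with an estimated correlation). Pluripotency genes had 11 of 12 higher (11 adjusted over the list alone), with Prdm14 at 3.41, Tbx3 at 3.18, Nodal at 2.58 and Sox2 at 2.40, and a median of 1.63 (camera adjusted p = 0.000895, adjusted p = 0.119 with an estimated correlation). Hox genes had 23 of 37 higher and 2 lower and a median of 1.52 (adjusted p = 8.32e-07, adjusted p = 0.157 with an estimated correlation). Tumour suppressor genes had 12 of 35 higher and 1 lower (12 and 1 adjusted over the list alone), with the WNT antagonist genes Sfrp5 and Sfrp1 at 3.40 and 3.28, Runx3 at 3.16 and Slit2 at 2.26 (median 0.74, adjusted p = 0.00146, adjusted p = 0.0107 with an estimated correlation). Camera called 17 of the 23 lists here, 16 of them higher, and 13 also with an estimated correlation, so the rise was not particular to these lists. Fewer genes were called with other processing. After quantile normalization 57 developmental, 10 Hox, 4 pluripotency and 6 tumour suppressor genes were higher, with medians of 0.83, 0.68, 0.77 and 0.14. In the series matrix values 49, 9, 5 and 6 were higher, and after normexp 75, 17, 6 and 10. Islet genes themselves had 2 of 18 higher and 1 lower: the glucokinase gene Gck rose by 1.86 (adjusted p = 0.00263) and Rfx6 fell by 1.21, while Pdx1, called with 1.43 ± 0.60 (adjusted p = 0.0436), had an SD of 3.06 between the lines and −0.73 without alphaTC. The islet list median of −0.09 had a mean of 0.06 and changed sign to 0.08 in the series matrix values and 0.10 with batch as a block (camera adjusted p = 0.932). Gck lost its call and Pdx1 as well with batch as a block. Housekeeping genes had 1 of 28 higher and 4 lower and a median of −0.64 (adjusted p = 0.00113, adjusted p = 0.131 with an estimated correlation).

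The limma fit called 3431 regions in the islet lines (2340 higher, 1091 lower) and 3077 with batch as a block (2056 higher, 1021 lower, 1910 and 462 shared). With the block the median of the 2340 higher regions went from 1.83 ± 0.30 (SE) to 1.88 ± 0.45. That of the 1091 lower ones went from −1.16 ± 0.27 to −1.09 ± 0.41. Normexp gave 2067 higher and 19 lower. The larger direction turned with the size limit, with 2933 higher and 4432 lower at a limit of 0.5 and 2973 and 4850 without a limit. The median over all regions was −0.35, −0.16 after normexp, −0.11 after quantile normalization and −0.21 in the series matrix values. Purified beta cells, a single array assumed to vary like the other classes, whose spread gives its errors and p-values, had 15 regions called (13 higher, 2 lower) and 23 without muscle replicate 1. Celsr3 was higher by 2.30 ± 0.24 (adjusted p = 1.56e-05), the homeobox gene Lmx1b by 2.43, Grin1 by 2.36, Cdh22 by 2.19, Unc13a by 1.99, the potassium channel gene Kcnh6 by 1.50, Ggh by 1.42 and Pvr by 1.36. Nr2f1 differed by −3.39 (adjusted p = 0.00909) and the sodium channel gene Scn8a by −2.45 (adjusted p = 0.0446). Most of these calls, Celsr3 and Ggh excepted, ended with batch as a block, although the sizes changed little. The median of the 13 higher regions was 1.42 and 1.45 with the block, and that of the 2 lower ones −2.92 and −2.74. Germ cell (median −1.79), imprinted (median −1.38) and hox (median −0.36) lists were placed lower in this 1 array by camera, and 0 of them were called with an estimated correlation. These medians moved with the scaling: germ cell genes had −0.54 after quantile normalization and −0.51 after normexp, imprinted genes −0.25 and −0.22, and hox genes −0.38 and −0.03. Of their genes 0 were called by limma over all regions, with 20, 7 and 10 at an unadjusted p under 0.05 and 19, 0 and 1 lower adjusted over the list alone. Quantile normalization called 159 regions higher and 50 lower and division by spread 157 and 60.

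Differences among the adult tissues were tested with limma's moderated F test over 16 arrays. The endocrine regulator gene Mnx1 (chromosome 5, 29800508 to 29800983, inside the gene) had a mean of 4.55 in pancreas and 3.71 in colon and between −0.56 and 0.64 in the other 6 tissues (adjusted p = 0.0151, n = 2 per tissue). The endoderm factor gene Foxa2 (chromosome 2, 147864276 to 147864668, downstream) had 3.08 in colon (adjusted p = 0.00112) and Pax8 4.10. The VIP receptor gene Vipr1 had 3.72 in colon and 2.69 in pancreas, Gata4 had 2.80 and 2.43, Lhx3 had 2.65 in pancreas and Gpx7 3.09 in pancreas. The others of the 12 called regions lay at Mir199b, Nrn1, Zfp423, Cahm and Llgl2. Colon differed from the other 7 tissues at 60 regions (58 higher, 2 lower) and pancreas at 9 (9 higher). These were also the only tissues with 2 male arrays: with sex as a covariate the F test called 2 regions, colon had 64 and pancreas 3, and with replicate number as a block the counts were 7, 47 and 5. After normexp all 3 counts were 0. Limma called 0 regions for brain, kidney, liver, lung, muscle and spleen, with 569, 173, 621, 280, 616 and 1289 at an unadjusted p under 0.05. Among the regions furthest below the other tissues, Casz1 differed by −2.81 in brain and −3.09 in liver and Hoxd4 by −2.41 and −2.50, without passing the test (adjusted p = 0.998 and 0.999). Epcam, an epithelial adhesion gene, differed by −2.14 in colon (adjusted p = 0.0517). The lowest named regions elsewhere were Phospho1 by −2.37 in pancreas, Sorbs3 by −1.82 in kidney, Ppm1h by −1.81 in lung, Espn by −2.03 in muscle and Mnx1 by −1.83 in spleen, none of them called. Without either colon array the F test called 0 regions and colon 4 or 6, without pancreas replicate 2 the F test called 6 and pancreas 0, and without pancreas replicate 1 pancreas had 23. Colon had 37 and 38 without either muscle array and 28 without muscle, where pancreas had 3. Pancreas had 3 without either colon array, 3 and 5 without either brain array, 4 without either kidney array, and 4 without liver replicate 1 or spleen replicate 2. At the preset correlation, adjusted over all lists and tissues, camera placed several lists apart. Germ cell genes were lower in muscle (median −0.93, adjusted p = 1.6e-14) and liver (−0.91, 6.94e-13) and higher in spleen (1.05, 2.34e-09). Imprinted genes were lower in liver (−0.96, 7.5e-14) and muscle (−0.84, 4.11e-12) and higher in spleen (0.92, 5.61e-08). Protocadherin genes moved the same way (−0.85 in muscle, −0.87 in liver and 0.98 in spleen). The spread of the arrays (percentiles 25 to 95) went with these medians. It was 2.6 and 3.7 in muscle, 2.8 and 3.6 in liver, and 5.1 and 5.0 in spleen. Enrichment of the arrays therefore cannot be told apart from a tissue difference at these lists. Limma called 0 genes of the germ cell and imprinted lists in these tissues. With an estimated correlation camera called 0 of the lists in any tissue (adjusted p between 0.855 and 0.965 for the lowest of each tissue).

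Female and male adult tissues differed at 242 of 385 X-linked regions (237 higher in females, 5 lower; 7 female and 9 male arrays, 5 tissues with both). The microRNA gene Mir505 had 3.72 ± 1.18 in female and −0.56 ± 0.36 in male arrays (SD), a difference of 4.24 (limma, adjusted p = 0.00852). Zic3, Htatsf1, Hmgb3, Lonrf3, Otud5, Tbl1x and Smc1a, genes of the X chromosome, were higher by 3.96, 3.88, 3.78, 3.75, 3.68, 3.65 and 3.53. On the autosomes 67 of 13444 regions were called, 26 higher and 41 lower, with Tmem267 at −3.57, 4833420G17Rik at −2.16, the rootletin gene Crocc at −2.08, Lhx5 at −1.44, Ssbp3 at −1.42, the serotonin receptor gene Htr5b at −1.40, Ttc28 at −1.23 and the dopamine receptor gene Drd2 at −1.19. The larger autosomal direction turned to higher with no size limit (211 higher, 102 lower) and with input well above background on every array (79 and 48). In all 5 tissues with both sexes the female array was replicate 1 and the male array replicate 2, scanned on another day. The female files of these tissues held 97651 probes and the male files 88737. With replicate number or scan day as a block, after normexp, or without either kidney array, 0 X-linked and 0 autosomal regions were called. At the 237 X-linked regions higher in females the median difference was 2.54, and 1.75 with replicate number and 2.01 with scan day as a block, above 0 at all 237 each time. The X-linked level stayed low in male replicate 1 of colon and pancreas (0.22 and 0.23) and high in female replicate 2 of lung (1.33), against replicate number as the only cause there. Without either brain array 137 X-linked regions were called and without either spleen array 114, and autosomal calls were 28 and 40 without either liver or muscle array.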

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

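Chosen only after the result was seen were the tests of array spread and of batch as the whole cause of the imprinted loss, of the batch of the teratomas and of the batch shared by placenta, islet lines and ES lines.

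Imprinted regions were lower in ES cells than in normal tissues, with a median of −1.19 over 23 genes. The median lay inside the middle 95% of 10000 random sets of regions matched on their normal level (−1.224 to −0.415), so that weaker enrichment on the ES arrays may contribute to its size. With each array divided by its spread the list median was −0.762, which leaves weaker enrichment open for the list. Of the 13 genes called lower 11 stayed called lower (Zrsr1 −4.24 and −4.19 after division, Mcts2 −4.26 and −3.91). The germ cell median moved from −1.40 to −0.32. Because the 13 genes were picked as lower in the same data, their count cannot decide whether spread was the whole cause. With batch as a block the median was −1.173 and 12 genes were called lower (Mcts2 −4.26 ± 0.45 and −3.68 ± 0.51 with the block) while the germ cell median moved from −1.40 to −0.83 and all calls from 1021 to 523, against batch as the whole cause. Within batches the median was between −1.413 and −0.991, which leaves a share of batch in its size open, as it does a biological loss of imprinting.

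Regions higher in ES cells were near the normal level in teratomas (0.134 and 0.006) but not in cells differentiated in culture. For C4 teratomas this did not hold in every setting: they lay within the replicate spread (0.169) of retinoic acid treated cells with input well above background on every array (0.635 and 0.667), at least 5 probes (0.523 and 0.665) and no size limit (0.272 and 0.346) and, as D3 teratomas (0.099), of mesoderm after normexp (0.159 and 0.24), and had 0.436 with batch as a block and 0.311 in the series matrix values. The ES lines scanned in the teratoma batch had ratios of 0.843 and 1.142 at these regions, which argues against that batch as the whole cause there. Each line was measured at regions called with the other ES line of that batch among the rest, which favours a high ratio. At regions lower in ES cells the teratoma ratio differed from that at higher regions by 0.091 and 0.181, as host cells in the tumours could bring about. The ratio at lower regions also followed the spread of the arrays, so this likeness does not single out host cells, and differentiation within the tumour stays open too, as untested.

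Regions higher in ES cells were also high in placentas and islet tumour lines. Teratomas, the E8.5 embryo and beta cells of the same batches had ratios between −0.085 and 0.134 there, against the shared batch as the cause. The median difference was 0.978 in Min6, above the middle 95% of 10000 matched random sets (upper end −0.208), with 1.26 in alphaTC, 1.43 in E14.5 and 1.09 in E19.5 placentas, against a general rise at unmethylated regions. That these samples may share a methylation pattern with ES lines is a hypothesis found and tested on the same data.

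Line TT2 had a median protocadherin level of 3.31 and the other 4 ES lines between 0.89 and 1.37. It was the 1 outlying sample in 44 groups tested, where chance gives an outlier in about 1 in 20 groups. Its single array had the largest spread of the ES arrays (3.84 against 2.51 to 3.06), so enrichment cannot be told apart from the line. The change from the own ES line differed between teratomas and cells in culture at 397 regions (358 higher, 39 lower in teratomas). Teratomas came only from lines C4 and D3, cells in culture only from TT2 and EB5, and they shared no batch. Line and batch therefore cannot be told apart from the way of differentiation. The teratoma calls against their own line fell to 0 after normexp and in the series matrix values. At X-linked regions higher in female tissues, male adult arrays had levels between 0.145 and 0.262 (9 arrays) and female ones between 1.33 and 4.136 (7 arrays). Embryos had 1.66 at E8.5 and 2.21 at E9.5, both labelled male but within the range of the female arrays. The E12.5 embryo, labelled female, had 4.21. Lines EB5 and J1 had 0.28 and 0.29, beta cells 0.94, and placentas, labelled female, 2.51 at E14.5 and 1.54 at E19.5.

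In 5 comparisons other splits of the same samples gave fewer calls than the real one. Only 1 of 100 splits, the real one, reached 1021 calls for ES cells (highest other 111), 1267 for cells in culture (250), 404 for embryos (2) and 242 X-linked calls for sex (0). For placentas 1 of 56 reached 1782 (379), with the replicate arrays of E19.5 counted apart. The splits did not keep batch, replicate number or scan day together, so they cannot exclude chance for samples that share these. Embryos fell to 9 calls with batch as a block. The 331 lower regions of embryos had a median of −1.67 ± 0.33 (SE) and −1.96 ± 0.84 with the block, so their calls ended because the error grew, while the 73 higher ones moved from 1.22 ± 0.29 to 0.76 ± 0.61. No embryo shared a batch with an adult tissue, so the block was estimated only through other sample types. It cannot decide between batch and an embryo difference, and batch stays open at both sets of regions. With replicate number as a block the X-linked median difference between sexes was 1.75 ± 0.69 (2.54 ± 0.44 without it) and all 237 regions stayed above 0, so the calls ended as the difference shrank and its error grew. The X-linked level followed sex also where replicate number or scan day did not: male replicate 1 of colon and pancreas had 0.218 and 0.226, female replicate 2 of lung 1.33, and male liver replicate 2, scanned on the day of that lung array, 0.16. This argues against replicate number or scan day as the whole cause at the X-linked regions. For the 67 autosomal calls (median size 1.17 ± 0.24, and 1.37 ± 0.39 with replicate number as a block) replicate number, scan day and the number of probes in the file stay open. The 9 splits of cells in culture against their own line are too few for a test (real 0, highest other 0).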

How the results depend on the processing

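The blocks for scan day and slide, the replicate block for sex, and the fits without lines C4 and D3 or embryos E8.5 and E9.5 were chosen only after the data were seen. The causes below were not tested, except that fewer regions were tested with dim probes left out (7341), at least 5 probes (8667) and the deposited scores (9589, size limit in SD units). Comparisons are ordered as ES cells, cells in culture, teratomas, embryos, placentas, islet lines, beta cells.

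Normexp gave 287, 80, 3, 60, 620, 2086 and 9 calls, 0 for teratomas against their own line, for tissues and for sex (X-linked and autosomal), and an ES-high median ratio of 0.359. Quantile normalization gave 577 for cells in culture, 1464 for islet lines, 209 for beta cells, 83 for teratomas against their line, 284 autosomal calls for sex and a ratio of 0.512. Division by spread gave 31 for teratomas, 217 for beta cells, a ratio of 0.618 and an enriched-region difference of 617.1 (exact permutation p = 0.000467). With dim probes left out the calls were 438, 495, 344, 218, 575, 1654 and 1, then 134 for teratomas against their line, 6 for tissues, 121 X-linked and 127 autosomal for sex. At least 5 probes gave 502, 550, 279, 222, 952, 2224 and 8, then 198, 6 for tissues and 28 autosomal, and medians of probes gave 4 for beta cells. The deposited scores gave 381, 293, 76, 189, 424, 1139 and 70, then 0 for teratomas against their line, 12 autosomal calls and a ratio of 1.018.

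No size limit gave 3703, 2443, 1323, 986, 4507 and 7823 (beta cells stayed at 15), 313 autosomal calls for sex and a ratio of 0.548. A limit of 0.5 gave 2633, 2034, 1309, 846, 4090 and 7365 (beta cells 15) and 312 autosomal calls for sex. Single probes gave 7962 for ES cells. The batch block gave 523, 547, 15, 9 and 543, then 2 for beta cells, with Piwil1 at 0.571 and Sycp2 at 1.358 reversed in placenta; it was not run for tissues and sex, whose arrays lie in 1 batch. The scan day block gave 252 for embryos, 3 for beta cells and 0 and 0 for sex, the slide block 3 for beta cells, and the type block 3 for beta cells and 1 for cells in culture against their line. Without C4 and D3 the ES count was 636 and without E8.5 and E9.5 the embryo count 265. Replicate numbers did not pair samples over all tissues (11 of 28 tissue pairs above r = 0.1, range −0.534 to 0.517, and −0.048 for ES and teratoma C4). In the 5 tissues with both sexes, however, they went with sex. As a block they gave 7 calls for tissues, 0 and 0 for sex and 1974 against 1890 for teratoma against ES C4. Sex as a covariate gave 2 for tissues, with 3 for pancreas. Of 87 list calls 38 held with an estimated correlation.

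Leaving out 1 unit or array gave 856 to 1232 calls for ES cells, 871 to 1332 for cells in culture, 5 (without C4) to 1182 (without D3) for teratomas, 334 to 417 for embryos, 1592 to 2145 for placentas, 2636 to 4228 for islet lines, 10 to 23 for beta cells (23 without muscle replicate 1), 0 to 3 for cells in culture against their line, 99 (C4) to 748 for teratomas against theirs, 0 (colon) to 16 for tissues, 0 (kidney) to 295 X-linked and 0 to 88 autosomal for sex, and ratios of 0.626 to 0.978. The named-gene values that reversed were those of Irx1, islet-derived samples against adult tissues, between −0.653 (without Min6) and 2.491 (without alphaTC), and of Pdx1, islet-derived samples against adult tissues, between −0.73 (without alphaTC) and 3.598 (without Min6). Of 2249 values of named genes under other settings 1952 kept direction and call, 281 lost the call, 14 gained it and 2 reversed; normexp ended 77 of 196 and the batch block 73 of 196. The share of input probes above background, from 62.5%, limits what dim probes can show.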

Other observations

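At regions lower in ES cells, beta cells had a median ratio of 0.794, endoderm 0.823 and mesoderm 0.77, while embryoid bodies had 0.361 and retinoic acid treated cells 0.676. Placentas had 0.192 and 0.207, teratomas 0.225 and 0.187, Min6 0.272 and alphaTC 0.365. Among the ES lines TT2 had 0.313, and EB5, J1, C4 and D3 had 0.782, 1.08, 1.126 and 1.242. This order followed the enrichment of the arrays: every type named here with a ratio of 0.365 or less had arrays with a spread (percentiles 25 to 95) of 3.80 or more, and every type with 0.676 or more had a spread of 3.52 or less. At regions higher in ES cells Min6 had 0.682, alphaTC 0.937, placentas 0.963 at E14.5 and 0.787 at E19.5, and beta cells 0.027.

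The first 2 principal components held 22.8% and 17.4% of the variance.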
